A study of Mus musculus with 4 samples.

How the data were processed

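Liver RNA of 12-week-old male C57BL/6 mice was sequenced in 4 libraries, 2 from wild-type (WT) and 2 from SREBP1c knockout (KO) animals, all fasted for 24 h and then refed for 12 h, per the labels. Groups and replicate numbers were taken from the sample titles. The labels give separate samples but do not say that each came from another animal, so p-values measure only the spread between these samples, which may be technical.

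The authors deposited one table of FPKM (fragments per kilobase of transcript and a fixed number of mapped fragments), with 1 value per RefSeq transcript and library, per the file headers. Bowtie and TopHat are named with the mm10 build in the submitters' processing notes, without versions. The program that computed FPKM, the annotation release and the use of strand are not given in the sources used here. The table held 33170 transcript rows of 23920 genes, and 5009 genes had several rows, up to 22. An FPKM value of a gene with several transcripts depends on how the program shared fragments between them, so a row can move while its gene does not. Rows of 8874 transcripts were at 0 in all 4 libraries. These included Alb and 18 of the 24 Mup rows, which the liver expresses at very high levels, so a 0 was read only as a gene being listed at 0. Symbols of 56 rows had been turned into dates and were restored through the gene number, and 23847 genes were matched by gene number to a RefSeq table of the same mouse assembly, which gave the coordinates.

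FPKM hides the number of fragments, but low values of single-transcript genes lay on steps of 1 fragment divided by the transcript length. These steps implied 23.2 M (mega) fragments for WT replicate 1, 21.2 M for WT replicate 2, 23.2 M for KO replicate 1 and 21.2 M for KO replicate 2. Between 66.5% and 71.4% of the low values lay within 0.1 of a whole fragment. The remainder did not, so no count test was run. Each group had 1 library of either depth.

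Differences were tested with limma 3.58.1 in R 4.3.3 (moderated test with an intensity trend) on log2(FPKM + 1), over rows with a mean of at least 1 FPKM, with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 difference is KO minus WT on the log2(FPKM + 1) scale, which understates the change of low genes. Folds are ratios of the group means of FPKM. The design written beforehand assumed 1 row per gene, while the table holds transcripts: rows were tested as deposited, and sums over the rows of a gene were an alternative. With 2 libraries against 2, an exact permutation test cannot go below a two-sided p of 0.333, so none was used for single genes. The 38 gene lists were tested with camera at a preset correlation of 0.01, with 1 row per gene (the one with the highest mean) and at least 5 measured members. Camera with an estimated correlation and fry with a direction were alternatives. Fry without a direction, added after the data were seen, asks whether members of a list differ either way.

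The genes named were fixed by a rule before the data were examined: Srebf1; the 14 largest differences in each direction past the threshold whose groups did not overlap, leaving out predicted-gene names, and, in a direction with fewer than 5, a fill to 10 by unadjusted p among genes with a log2 difference of at least 1; up to 4 members of each list with the smallest p; and a set of lipid, glucose and sterol genes whatever their result, 3 of which are left out of the text for a reason unrelated to their values. The gene lists, the tests and all alternatives were also fixed then, except that the removal of rows near Srebf1, a robust variance prior and the sums over rows for single genes and lists were added after the data were seen. Alternatives were pseudocounts of 0.1 and 0.5, no filter, a minimum of 5 FPKM, upper-quartile and quantile scaling, no trend, the replicate number as a block, each library left out, a threshold of 0.1, a minimum fold of 1.5 and summed rows.

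The tests were run first on simulated data with the means of the 11494 rows tested, in 20 runs with 200 changed rows each. Variances were drawn from the prior that limma fitted to these rows, with normal noise. Of rows changed by 1 log2 unit 42.7% were called, of rows changed by 2 units 91.2%, of rows changed by 3 units 96.9% and of rows changed by 5 units 99.3%, and 5% of the calls were unchanged rows. In 1 of 20 runs without any change at least 1 row was called. A list of 25 genes moved by 0.5 was called in 20 of 20 runs, and 0 of 620 unmoved lists were. These simulated genes varied independently, which real genes of a list do not. They also followed the model that the limma test assumes, so these rates do not check it on data with an outlying library. Tables and figures were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.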

Results

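The liver transcriptome was compared between wild-type (WT) mice and mice without SREBP1c (KO), the insulin-responsive transcription factor of hepatic fatty acid synthesis that is encoded by Srebf1. Male C57BL/6 mice aged 12 weeks had been fasted for 24 h and refed for 12 h, a state in which lipogenic genes are normally high. There were 2 WT and 2 KO libraries. A mean of at least 1 FPKM was reached by 11494 transcript rows of 9638 genes.

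Srebf1 (NM_011480, chromosome 11, 60199084 to 60224186, mm10) was measured first, as the targeted gene. It had 63.7 and 58.2 FPKM in the WT libraries and 8.63 and 6.97 FPKM in the KO libraries, or 60.9 ± 3.91 against 7.80 ± 1.17 FPKM (SD, n = 2 each), a 7.81-fold lower mean in KO. The log2 difference was −2.82 with a standard error of 0.14 (limma adjusted p = 0.0182), lower in both KO libraries. The table has a single Srebf1 row, which does not separate SREBP1c from SREBP1a, the other product of the gene. The adjusted p rose to 0.186 without a filter on low values, 0.527 without WT replicate 1 and 0.422 without WT replicate 2. It ranged from 0.00172 to 0.527 over all alternatives, while the log2 difference stayed between −2.96 and −2.68 with any library left out.

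The comparison of KO with WT over all rows asks which other transcripts differ. Beside Srebf1, 4 rows fell in KO and none rose past the limma threshold. Pttg1, which encodes securin, a regulator of sister chromatid separation, had 26.5 ± 2.15 FPKM in WT and 1.51 ± 0.223 FPKM in KO (SD, n = 2 each; log2 difference −3.46, SE 0.13, adjusted p = 0.0174), a 17.6-fold lower mean. It lies on chromosome 11 at 43420244 to 43427463. A transcript of Mrpl55, a mitochondrial ribosomal protein gene at 59202486 to 59206138 on the same chromosome, had 10.3 and 9.56 FPKM in WT and 0.33 and 0.62 FPKM in KO (log2 difference −2.89, adjusted p = 0.0182). The sum over the 5 rows of Mrpl55 differed only by −0.18 (adjusted p = 0.774). Mir692-2 (chromosome 4) was listed at 110.5 and 61.8 FPKM in WT and at 0 in both KO libraries (adjusted p = 0.0182). Its row is a short microRNA precursor with a numbered copy in its name, and its value is uncertain. The last of the 5, 2610507I01Rik, a non-coding RNA directly beside Mrpl55 (59197793 to 59202431), fell outside the naming rule and was named after its values were seen: 6.14 and 5.71 FPKM in WT and 0.15 and 0.10 FPKM in KO (log2 difference −2.62, adjusted p = 0.0182). At an unadjusted p under 0.05, limma gave 453 rows higher and 355 lower in KO, 808 in all against 575 by chance. The groups did not overlap in 37.9% of rows, against 33.3% by chance. The count of 5 became 0 without WT replicate 1 or without WT replicate 2, 23 without KO replicate 1, 13 without KO replicate 2, 3 with a pseudocount of 0.1 and 0 without a filter.

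**Figure D1:**
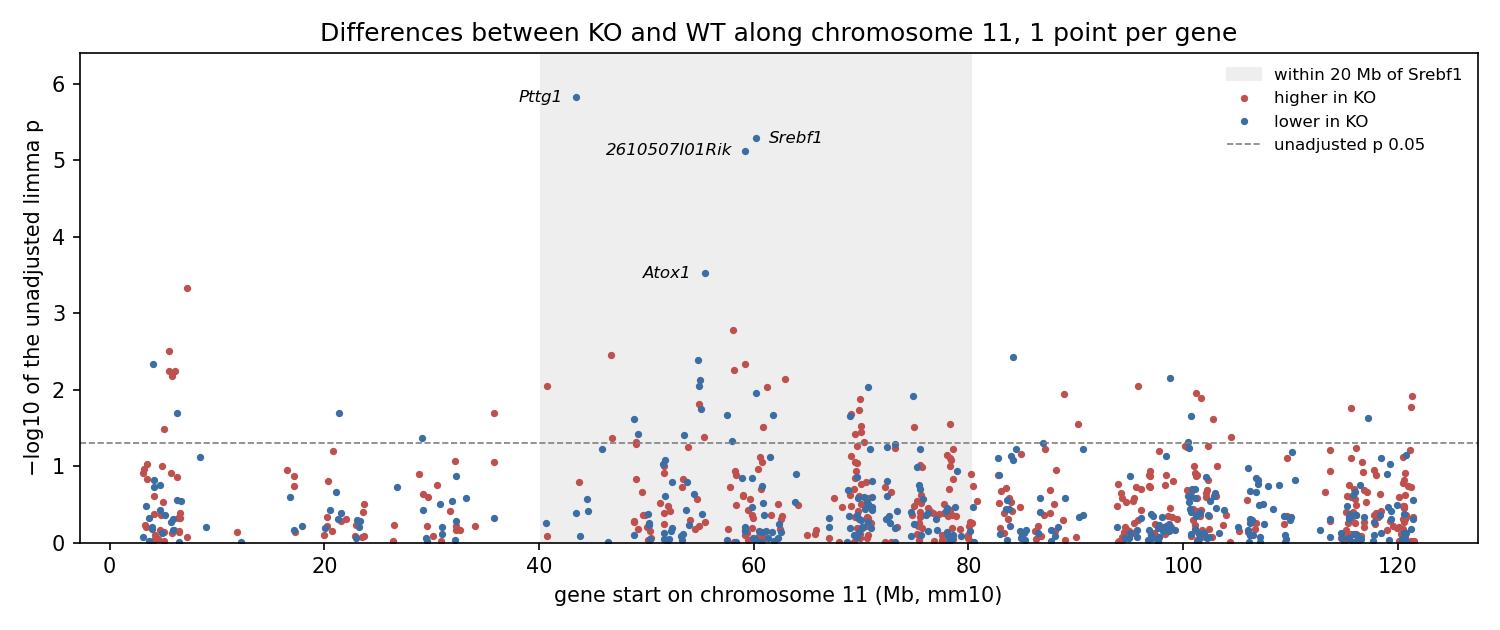
Position of each measured gene on chromosome 11 in Mb (mm10, x axis) against −log10 of its unadjusted limma p (y axis), 1 point per gene for its most abundant transcript, colored by direction, with the 20 Mb on either side of Srebf1 shaded and the dashed line at p 0.05. Pttg1, Srebf1 and 2610507I01Rik stand above all other genes of the chromosome, and all lie in the shaded stretch.

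None of the following genes passed the threshold. They filled the naming rule by unadjusted p, with KO and WT values that did not overlap. Obp2a, an odorant-binding lipocalin gene, had 5.33 ± 0.239 FPKM in WT and 32.1 ± 10.4 FPKM in KO (log2 difference 2.35, adjusted p = 0.238). The limma adjusted p of Obp2a was 0.0491 with the rows of each gene summed. Obp2a has a single row, so its log2 difference stayed at 2.35 there and its adjusted p moved only with the other genes of the fit. The log2 difference was 2.03 without KO replicate 1 and 2.68 without KO replicate 2. Erdr1 had 5.02 and 6.33 FPKM in WT and 14.4 and 12.9 in KO. Derl3 had 9.07 and 11.1 in WT and 21.2 and 23.9 in KO, and Fam25c had 27.2 and 30.6 in WT and 56.3 and 73.9 in KO. Single rows of Slc38a10, C1qtnf1, Irak2, Fam118b, Paqr7 and Sparc were higher in KO by 1.59, 1.35, 1.56, 1.23, 1.32 and 1.31 on the log2 scale. The sums over the rows of these genes differed by 0.24, 0.19, 0.12, 0.43, 0.01 and 0.60. On the lower side, Acacb, the mitochondrial acetyl-CoA carboxylase gene, had 12.2 and 8.72 FPKM in WT and 2.47 and 1.93 FPKM in KO (log2 difference −1.83, adjusted p = 0.238). Camk1d had 4.44 and 5.02 FPKM in WT and 1.13 in each KO library, and Cyp17a1, the steroid 17α-hydroxylase gene, 3.59 and 3.15 in WT and 0.47 and 0.68 in KO. With summed rows these 2 passed, at limma adjusted p = 0.0248 and 0.0374. Cyp17a1 has a single row, and its log2 difference of −1.48 did not change, so its adjusted p moved only with the other genes of the fit. Arrdc3 had 7.32 and 8.66 FPKM in WT and 2.93 and 2.95 in KO. Atox1, a copper chaperone gene on chromosome 11, had 285 and 318 in WT and 147 and 149 in KO. A row of St5 differed by −1.40 and the sum of its rows by −0.05.

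The 38 gene lists ask whether groups of related genes moved together. With camera at the preset correlation, 14 of the 32 lists with enough measured genes passed, 6 higher and 8 lower in KO. None passed with an estimated correlation or with fry in 1 direction, so each directional call below rests on the preset value. The p given below with an estimated correlation is that of camera before adjustment over the lists. After adjustment it was 0.896 for each list that passed at the preset value. The estimated correlations of those lists ran from −0.0227 for clock genes to 0.955 for cholesterol genes, against the preset 0.01. Fry without a direction, added after the data were seen, passed 2 lists, genes next to Srebf1 (adjusted p = 0.015) and periportal hepatocytes (0.0328). KO replicate 2 stood apart from the other libraries in several lists. Without it the camera direction turned in 4 of the 14 lists.

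**Figure D2:**
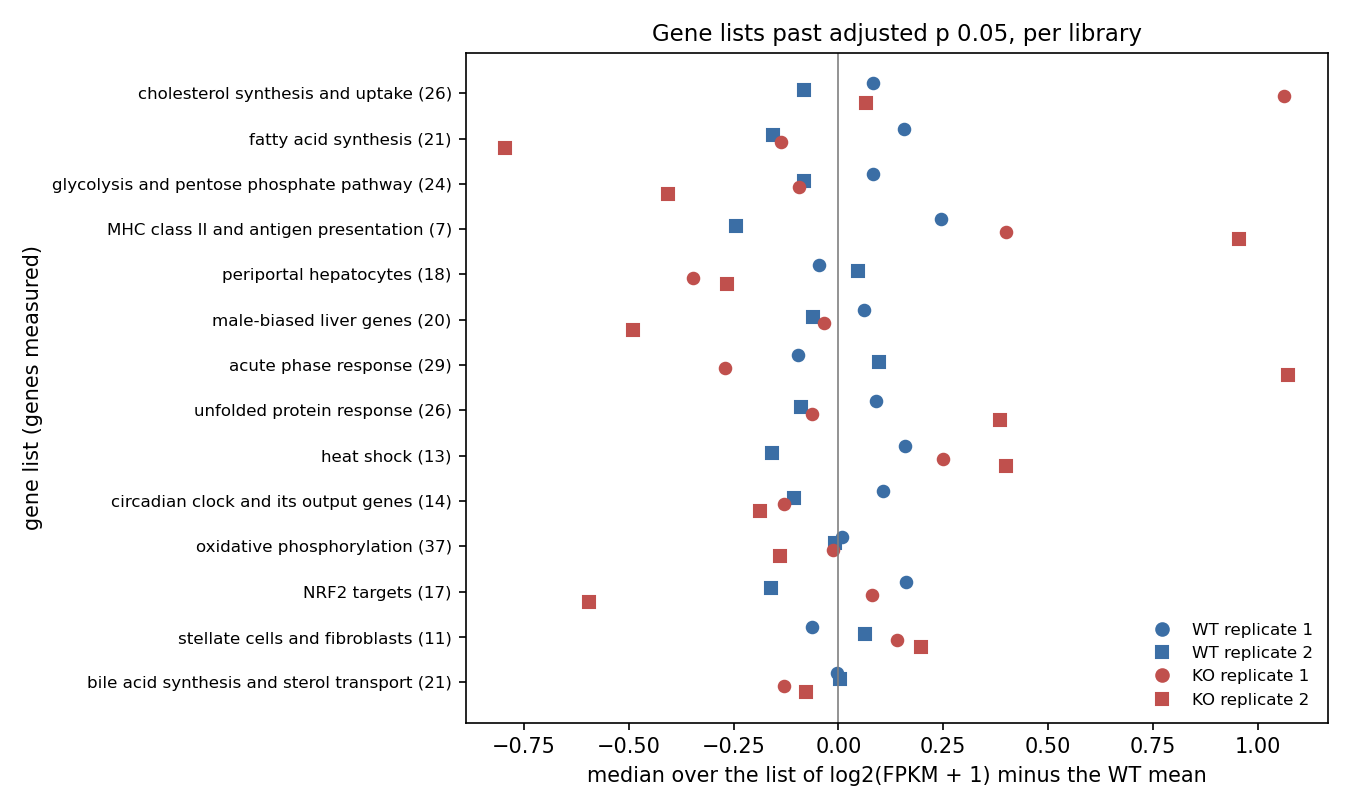
Median over each gene list of log2(FPKM + 1) minus the WT mean of the same gene (x axis), per library, for the 14 lists that passed camera at the preset correlation, with the number of genes measured in parentheses. For cholesterol synthesis KO replicate 1 lies at 1.06 and KO replicate 2 at 0.07; for the acute phase response they lie at −0.27 and 1.07.

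Genes of fatty acid synthesis were lower in KO as a list (median log2 difference −0.48, camera adjusted p = 1.65e-07; p = 0.275 with an estimated correlation). Of 21 measured members 18 had a negative difference, 9 were lower in both KO libraries than in both WT libraries (16.7% by chance), none passed over all genes and 4 passed adjusted over the list alone. With the replicate number as a block Thrsp passed over all genes (adjusted p = 0.0186). Thrsp, a regulator of lipogenesis, had 450 and 188 FPKM in WT and 81.8 and 32.4 in KO. Gpam, which starts glycerolipid synthesis, had 69.1 and 51.5 in WT and 27.8 and 22.0 in KO, and Acsl5 122 and 103 in WT and 76.8 and 66.3 in KO. Of the core enzymes, Fasn had 136 and 72.0 FPKM in WT and 67.2 and 22.4 in KO (log2 difference −1.32, SE 0.58). Scd1 had 291 and 149 in WT and 102 and 92.2 in KO (−1.09, SE 0.32). Acaca had 24.4 and 13.1 in WT and 12.9 and 8.01 in KO, and Acly 41.7 and 34.2 in WT and 31.2 and 25.3 in KO. Elovl6 overlapped between the groups, with 35.6 and 17.6 in WT and 22.5 and 7.94 in KO. Pnpla3 was near the floor in all libraries, with a mean of 0.0791 FPKM. The list median was −0.79 in KO replicate 2, −0.14 in KO replicate 1 and −0.16 in WT replicate 2, each relative to the WT mean. Without KO replicate 2 the median difference was −0.14 and the call was lost (adjusted p = 0.0655). It was −0.28 without WT replicate 1, −0.74 without WT replicate 2 and −0.79 without KO replicate 1. The log2 difference of Fasn ran from −2.10 without KO replicate 1 to −0.55 without KO replicate 2, and that of Scd1 was −0.61 without WT replicate 1.

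**Figure D3:**
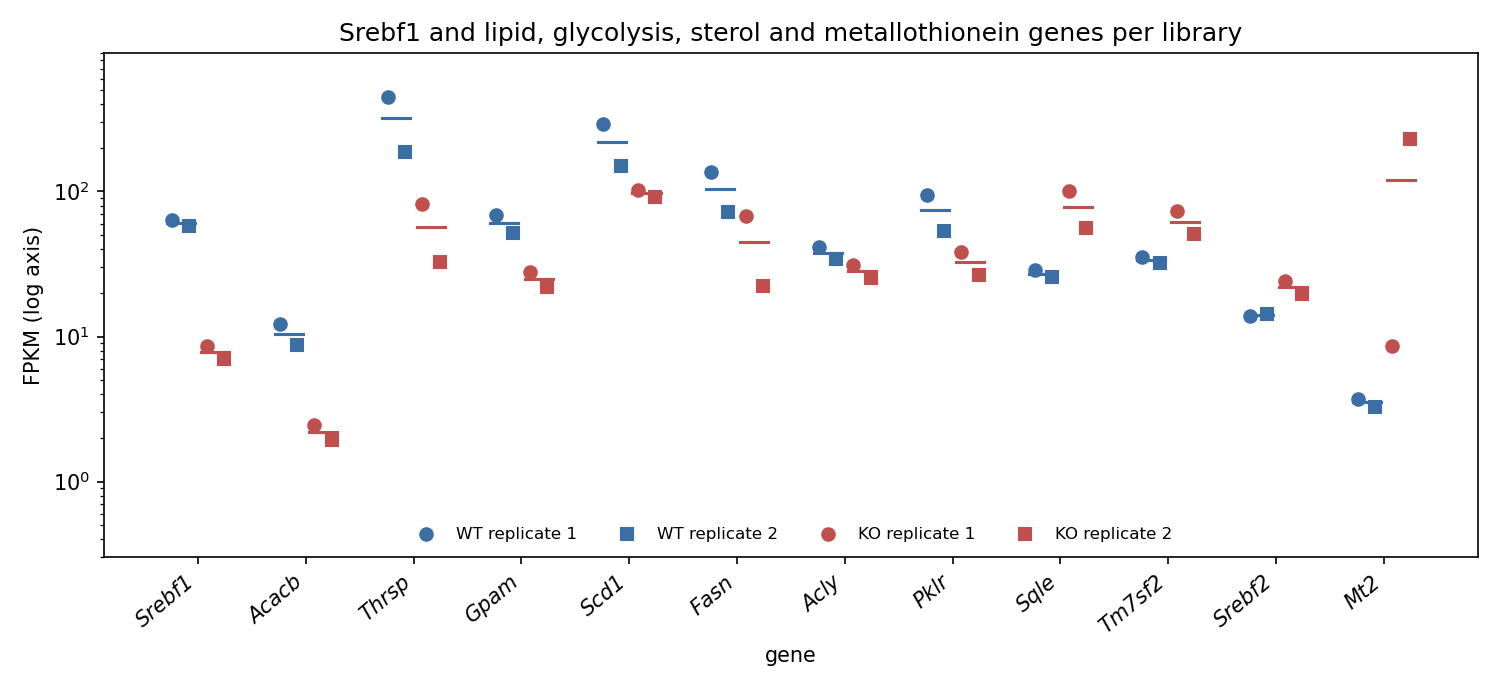
FPKM on a log axis of 12 genes (x axis) in each of the 4 libraries, with the group mean as a bar. Srebf1 lies between 58.2 and 63.7 FPKM in WT and between 6.97 and 8.63 in KO, while the 2 WT libraries differ from each other in Fasn (136 and 72.0) and Scd1 (291 and 149).

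Glycolysis and pentose phosphate genes were also lower in KO as a list (24 measured, median −0.23, adjusted p = 6.37e-06; p = 0.227 with an estimated correlation). Of these 19 had a negative difference, and none passed over all genes or adjusted over the list alone. Pklr, liver pyruvate kinase, had 95.3 and 53.4 FPKM in WT and 38.5 and 26.7 in KO. Slc2a2, the hepatic glucose transporter, had 92.8 and 92.1 in WT and 57.9 and 38.9 in KO. Pfkfb1 had 16.2 and 17.6 in WT and 10.9 and 9.57 in KO, and Khk, ketohexokinase, 465 and 358 in WT and 302 and 234 in KO. Mlxipl, which encodes ChREBP, overlapped between the groups, with 49.2 and 38.1 in WT and 42.8 and 32.5 in KO. With 1 library left out the list median ran from −0.41 without KO replicate 1 to −0.10 without KO replicate 2. It was −0.13 without WT replicate 1 and −0.38 without WT replicate 2. Relative to the WT mean, KO replicate 1 lay at −0.095 and WT replicate 2 at −0.082. By the list median, KO replicate 1 was thus hardly lower than a WT library. Of the 24 genes, however, 13 were lower in both KO libraries than in both WT libraries (16.7% by chance).

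Genes of cholesterol synthesis and uptake were higher in KO as a list (26 measured, median 0.61, adjusted p = 1.65e-07; p = 0.322 with an estimated correlation). Of these 24 had a positive difference, 13 were higher in both KO libraries than in both WT libraries (chance gives 16.7% in each direction), and none passed over all genes or adjusted over the list alone. Sqle, squalene epoxidase, had 28.8 and 25.6 FPKM in WT and 100 and 56.4 in KO. Tm7sf2 had 35.2 and 32.3 in WT and 72.8 and 50.5 in KO, Hsd17b7 10.9 and 8.91 in WT and 24.8 and 15.0 in KO. Srebf2, which encodes SREBP2, had 13.9 and 14.3 in WT and 24.2 and 19.7 in KO. Insig1 had 91.3 and 100.3 in WT and 94.5 and 61.8 in KO, and Insig2 262 and 225 in WT and 244 and 161 in KO. The median was 1.06 without KO replicate 2 and 0.07 without KO replicate 1, and the list passed in both cases (adjusted p = 1.05e-36 and 0.0457). The median of KO replicate 2 (0.065) lay within the central 95% of random lists of matched expression (−0.123 to 0.077) and below WT replicate 1 (0.083), while Sqle, Tm7sf2, Hsd17b7 and Srebf2 were higher in KO replicate 2 too than in both WT libraries.

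The list of triglyceride synthesis and lipid droplet genes did not pass (20 measured, median 0.03, adjusted p = 0.898), with members on both sides: none passed over all genes and 6 passed adjusted over the list alone. Lpin2 had 13.9 and 14.1 FPKM in WT and 7.60 and 7.27 in KO, and Plin3 21.9 and 24.4 in WT and 16.2 and 16.4 in KO. Fitm1, which takes part in lipid droplet formation, had 25.7 and 26.3 in WT and 39.1 and 44.1 in KO. The leading row of Cd36, a fatty acid transporter, had 2.80 and 2.03 in WT and 5.95 and 10.3 in KO. That row differed by 1.39 on the log2 scale and the sum over its 5 rows by 0.83. Bile acid synthesis and sterol transport was lower as a list (21 measured, median −0.06, mean −0.14, adjusted p = 0.0367; p = 0.123 with an estimated correlation), with none past over all genes or adjusted over the list alone. Of its members 12 had a negative and 9 a positive difference. Slc10a1, the bile acid importer, had 357 and 334 FPKM in WT and 243 and 188 in KO. Abcg5 went the other way, with 12.3 and 17.7 in WT and 19.8 and 24.8 in KO. Nr1h4, the bile acid receptor, had 44.1 and 31.5 in WT and 25.4 and 21.3 in KO. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 18.8 and 4.17 in WT and 5.90 and 2.63 in KO. That call was lost without WT replicate 2 (adjusted p = 0.28) and without KO replicate 2 (0.13, median −0.13), and the median was −0.12 without WT replicate 1. It was also lost without a filter, with quantile scaling and with summed rows.

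Gluconeogenesis and fatty acid oxidation did not pass (adjusted p = 0.875 and 0.941). Pck1 had 170.0 and 300.0 FPKM in WT and 229 and 994 in KO. Fgf21 had 1.06 and 0.29 in WT and 0.96 and 5.71 in KO, and Cpt1a 28.4 and 36.2 in WT and 33.6 and 52.2 in KO. KO replicate 2 was the highest library for each. G6pc had 195 and 156 in WT and 171 and 193 in KO, and Ppara 6.73 and 8.94 in WT and 4.31 and 10.4 in KO. Insulin signalling did not pass either (adjusted p = 0.557), with Irs2 at 3.54 and 3.39 FPKM in WT and 2.40 and 2.99 in KO.

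Among hepatocyte programmes, periportal genes were lower in KO (18 measured, 13 of them negative, median −0.33, adjusted p = 4.81e-05; p = 0.0607 with an estimated correlation), with 1 past adjusted over the list alone and none over all genes. Cps1, which starts the urea cycle, had 620 and 621 FPKM in WT and 362 and 400 in KO, and Uroc1 120 and 119 in WT and 86.2 and 92.3 in KO. The list passed without each library in turn, while pericentral genes did not pass (adjusted p = 0.439). Male-biased genes were lower as a list (20 measured, 17 negative, median −0.29, adjusted p = 5.05e-04; p = 0.31 with an estimated correlation), with none past over all genes or adjusted over the list alone. Slco1a1 had 70.5 and 50.9 in WT and 42.4 and 42.0 in KO. Its median was −0.49 in KO replicate 2 and −0.04 in KO replicate 1, and the call was lost without KO replicate 2 (adjusted p = 0.723).

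NRF2 targets (17 measured, median −0.26, adjusted p = 0.031; p = 0.508 with an estimated correlation) and oxidative phosphorylation (37 measured, median −0.08, adjusted p = 0.023; p = 0.57 with an estimated correlation) were lower, with none past over all genes or adjusted over the list alone. Of the NRF2 targets 14 had a negative and 3 a positive difference. Only 1 of the 17, Osgin1, was lower in both KO libraries than in both WT libraries (16.7% by chance), with 379 and 256 FPKM in WT and 199 and 143 in KO. Of the oxidative phosphorylation genes 26 had a negative and 11 a positive difference. Uqcrc2 had 174 and 164 in WT and 149 and 141 in KO, while Uqcrq had 572 and 614 in WT and 698 and 673 in KO. Without KO replicate 2 the adjusted p of these lists was 0.374 and 0.827 and camera's direction turned, at medians of 0.08 and −0.01. NRF2 targets also lost the call without WT replicate 1 (adjusted p = 0.396, median −0.06), and their median was −0.43 without WT replicate 2 and −0.60 without KO replicate 1, and the call was also lost without a filter. Oxidative phosphorylation lost it without WT replicate 2 (adjusted p = 0.312), and its median was −0.14 without KO replicate 1.

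Circadian clock genes were lower in KO as a list (14 measured, 10 negative, median −0.08, mean −0.25, adjusted p = 0.023; p = 0.104 with an estimated correlation), with none past over all genes or adjusted over the list alone. Nr1d1, which encodes the clock repressor REV-ERBα, had 9.46 and 11.7 FPKM in WT and 1.32 and 4.16 in KO. Nr1d2 had 3.71 and 4.64 in WT and 1.55 and 2.99 in KO, and Cry2 5.79 and 6.81 in WT and 4.06 and 4.18 in KO. Cry1 had 8.18 and 7.31 in WT and 9.32 and 7.82 in KO. The call was lost without WT replicate 1 (adjusted p = 0.153, median 0.02) and without KO replicate 2 (0.0692, median −0.13). The median was −0.24 without WT replicate 2 and −0.19 without KO replicate 1. It was also lost with summed rows.

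Acute phase genes were higher in KO as a list (29 measured, 28 positive, median 0.33, adjusted p = 6.85e-04; p = 0.49 with an estimated correlation), with none past over all genes or adjusted over the list alone. The list median was 1.07 in KO replicate 2 and −0.27 in KO replicate 1. Mt2, a metallothionein, had 3.74 and 3.29 FPKM in WT and 8.67 and 230.3 in KO. Saa3 had 3.66 and 3.40 in WT and 4.01 and 20.5 in KO, and Cebpb 45.9 and 53.5 in WT and 72.0 and 128 in KO. Without KO replicate 2 the list was lower in KO (median −0.27, adjusted p = 1.79e-04), and without WT replicate 1 the call was lost (0.0854). Its median was 0.55 without WT replicate 2 and 1.07 without KO replicate 1.

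The unfolded protein response was higher (26 measured, median 0.17, adjusted p = 0.0169; p = 0.479 with an estimated correlation), with 2 past adjusted over the list alone and none over all genes. Atf5 had 289 and 263 FPKM in WT and 431 and 465 in KO, and the leading row of Xbp1 73.6 and 73.8 in WT and 105 and 106 in KO. That row of Xbp1 differed by 0.51 on the log2 scale and the sum over its 2 rows by 0.26. The list median was 0.39 in KO replicate 2 and −0.06 in KO replicate 1, and the call was lost without KO replicate 2 (adjusted p = 0.723, direction turned) and without WT replicate 2 (0.362, median 0.08). Its median was 0.26 without WT replicate 1 and 0.39 without KO replicate 1. Heat shock genes were higher (13 measured, median 0.24, adjusted p = 0.023; p = 0.213 with an estimated correlation), with 2 past adjusted over the list alone and none over all genes. Of the 13 heat shock genes 8 had a positive and 5 a negative difference. Dnajb1 had 5.84 and 6.33 in WT and 12.0 and 12.7 in KO, and Hspa8 403 and 361 in WT and 623 and 700 in KO. The call was lost without KO replicate 1 (adjusted p = 0.182, median 0.40) and without WT replicate 2 (0.443, median 0.13), and the median was 0.44 without WT replicate 1. It was also lost with a minimum of 5 FPKM and with summed rows.

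Among genes of other liver cells, MHC class II and antigen presentation was higher in KO (7 measured, 7 positive, median 0.68, adjusted p = 4.81e-05; p = 0.205 with an estimated correlation), with 2 past adjusted over the list alone and none over all genes. H2-Ab1 had 12.1 and 9.31 FPKM in WT and 17.8 and 24.1 in KO. H2-Eb1 had 7.41 and 4.96 in WT and 11.3 and 14.1 in KO, and Cd74, the invariant chain, 34.8 and 24.5 in WT and 38.8 and 57.6 in KO. The list median was 0.92 without WT replicate 1, 0.43 without WT replicate 2, 0.96 without KO replicate 1 and 0.40 without KO replicate 2. Between the WT libraries, replicate 2 minus replicate 1, the median difference was −0.49. Relative to the WT mean, the list median was 0.24 in WT replicate 1, −0.24 in WT replicate 2 and 0.40 in KO replicate 1. Of the 7 genes 5 were higher in both KO libraries than in both WT libraries (16.7% by chance). Markers of Kupffer cells and macrophages did not pass (adjusted p = 0.51), with a list median of −0.20 in KO replicate 1 and 0.55 in KO replicate 2. They passed as higher without KO replicate 1 (adjusted p = 1.05e-05, median 0.55) and as lower without KO replicate 2 (0.0143, median −0.20). Stellate cell markers were higher (11 measured, median 0.12, adjusted p = 0.031; p = 0.209 with an estimated correlation), with none past over all genes or adjusted over the list alone. Colec11 had 8.08 and 9.22 FPKM in WT and 11.9 and 13.3 in KO. That call was lost without WT replicate 1 (0.396, median 0.06), KO replicate 1 (0.0864, median 0.20) or KO replicate 2 (0.156), and the median was 0.19 without WT replicate 2. It was also lost without a filter and with summed rows. Cholangiocyte markers did not pass (6 measured, adjusted p = 0.467), with 1 past adjusted over the list alone: Spp1, osteopontin, had 20.9 and 19.6 FPKM in WT and 44.3 and 35.4 in KO.

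The other lists did not pass. Cell cycle genes had an adjusted p of 0.242 (7 measured, 2 past adjusted over the list alone), with Cdkn1a, the p21 gene, at 23.4 and 21.7 FPKM in WT and 34.7 and 47.8 in KO. Adjusted p was 0.225 for immediate-early genes, 0.439 for sinusoidal endothelial cells, extracellular matrix, erythroid cells and xenobiotic metabolism, 0.51 for the interferon response, 0.557 for phosphatidylcholine metabolism, 0.662 for lipoproteins and 0.912 for ribosomal proteins, with none of their members past adjusted over the list alone. With 1 library left out some of these passed: sinusoidal endothelial cells as higher (median 0.18) and xenobiotic metabolism as lower (−0.11) without KO replicate 1, immediate-early genes (−0.37) and erythroid cells (−0.77) as lower without WT replicate 2, and the interferon response as higher without WT replicate 1 (0.23) or KO replicate 1 (0.10). Ribosomal proteins passed as lower without KO replicate 1 (−0.10) and as higher without KO replicate 2 (0.13). Genes next to Srebf1 (18 measured) had none past the threshold either over all genes or adjusted over the list alone, and a camera adjusted p of 0.874, with 10 members higher and 8 lower in KO. Without a direction they passed with fry (adjusted p = 0.015). Too few members were measured of adipocytes (4), female-biased genes (3), neutrophils (2), exocrine pancreas (1), T and NK cells (1) and B and plasma cells (0) for a test. Cfd, the complement factor D gene of the adipocyte list, fell under the naming rule by its small p. The choice to print it was made after its values were seen. It had 0.40 and 0.06 FPKM in WT and 2.25 and 19.7 in KO (limma adjusted p = 0.645). Fabp4 of the same list had 22.9 and 14.3 in WT and 22.5 and 21.8 in KO.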

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

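The removal of rows near Srebf1, the robust variance prior, the sums over rows for single genes and lists and fry without a direction were chosen only after the result was seen; the other alternatives were planned. The 5 rows past the threshold, all lower in KO, became 3 (3 lower) with a pseudocount of 0.1, 0 (0 lower) without a filter on low values, where more rows are tested, and 1 (1 lower) without the rows within 20 Mb of Srebf1, where Srebf1 itself is left out and has no value. Summing rows gave 1 gene higher in KO, Obp2a, which has a single row. With 1 library left out the count ran from 0 to 23, with 0 to 17 higher and 0 to 6 lower. Such fits have 1 residual degree of freedom, and the lone library of a group is assumed to vary like the other group. Srebf1 lost its call without a filter (−2.82) and without either WT library, with a range of −2.96 to −2.68 over the left-out libraries. The 14 lists became 0 with an estimated correlation, 0 with fry, 2 with fry without a direction, 10 with summed rows, 12 without a filter, 12 with a minimum of 5 FPKM, 13 with quantile scaling and 8 to 17 with 1 library left out. Summed rows ended the calls of bile acid, clock, heat shock and stellate cell genes, no filter those of bile acid, NRF2 and stellate cell genes, the minimum of 5 FPKM that of heat shock and quantile scaling that of bile acid genes. At the minimum of 5 FPKM another of the 14 lists had too few measured genes for a test. With 1 library left out, the median ranged from −0.60 to 0.081 for NRF2 targets, −0.062 to 0.39 for the unfolded protein response, −0.27 to 1.07 for the acute phase response and −0.14 to −0.014 for oxidative phosphorylation, whose camera direction turned. The log2 difference ranged from −0.11 to 0.22 for G6pc, −0.72 to 0.38 for Ppara, −0.59 to 0.008 for Insig2, −0.022 to 0.49 for Hmox1, −0.63 to 3.77 for Lcn2 and −1.11 to 4.02 for Saa1. Summing rows gave 0.22 for Ppara. The cause of these shifts was not tested. Of 932 other values for single genes 919 kept their direction and side of the threshold, as did 116 of 153 for lists. With 1 library left out these were 400 of 424 for genes and 37 of 56 for lists, while 15 lost the call and 4 turned. The counts for genes are high because nearly all of the 106 genes were never past the threshold. The replicate number as a block gave 5 rows and 15 lists, with Srebf1 at −2.82 (adjusted p = 0.0137); Thrsp passed and 2610507I01Rik did not. Same-numbered libraries deviated with a correlation of 0.113 over all rows in 2 pairs, so the numbers were not taken as a pairing. For single lists this varied. Replicate 2 was below replicate 1 in both groups for fatty acid synthesis (median differences −0.313 in WT and −0.395 in KO), but not for MHC class II (−0.489 and 0.415). A factor shared by same-numbered libraries, whose implied depths also match, therefore stays open for the fatty acid genes. Depth differed little between libraries, and of simulated changes of 1 log2 unit 42.7% were called.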

Other observations

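The tests on chromosome 11, on KO replicate 2 alone as the source of the lower fatty acid list, on sequencing depth and on other splits of the libraries were chosen only after the result was seen; those on clock phases and neutrophils were written before their values were seen. The genes named in this part outside the naming rule were chosen after their values were seen.

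Chromosome 11 around Srebf1 held other genes with differing values, none past the threshold. Cnot8, a subunit of the deadenylase complex, differed by 0.62 on the log2 scale, with 31.7 and 31.6 FPKM in KO. Igtp, an interferon-induced GTPase, had 13.1 and 8.28 in WT and 21.2 and 23.4 in KO. Aldh3a2, the fatty aldehyde dehydrogenase, had 77.1 and 77.5 in WT and 136.6 and 105 in KO. Anxa6 had 33.1 and 33.8 in WT and 22.9 and 25.3 in KO, and Lyrm7 2.48 and 1.57 in WT and 0.53 and 0.34 in KO.

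With genes left out whose most abundant row was called, 11.8% of the 306 genes within 20 Mb of Srebf1 had an unadjusted p under 0.05, against 5.67% of the rest of the genome, an odds ratio of 2.22 (exact 95% interval 1.5 to 3.19), and 5.42% on the rest of chromosome 11. Of 127 windows of 40 Mb elsewhere, which overlap and so are not separate stretches, 1 had as high a share (12.5%). The window next to it had 11.57%. On chromosome 11 the highest share, 15.53%, was in a window centered at a lower coordinate than Srebf1. The odds ratio was 1.79 with summed rows and 2.16 with Mrpl55, whose less abundant row was called, left out as well. An effect on the genes directly beside the locus alone is argued against by an odds ratio of 2.25 (1.48 to 3.32) for genes 2 to 20 Mb away, with called genes kept in. Variants that stop KO reads from mapping are argued against as the source of all 38 genes under that p in the stretch. Of these 44.7% were lower in KO (28.6% to 61.7%), and 236 of 528 such genes elsewhere, with called genes left out. Since 5.67% of genes elsewhere also had such a p, variants stay open for a part of the 38. They stay open for the rows past the threshold too, which beside Srebf1 were lower in 3 of 3 cases. Of the 3, 1 is the less abundant Mrpl55 row. The most abundant Mrpl55 row was higher in KO, with 9.92 and 9.57 FPKM in WT and 15.9 and 13.9 in KO. The sum over the rows differed by −0.18, so the fall of 1 row need not be a loss of reads. A candidate explanation is a stretch of chromosome 11 that came along with the targeted allele and differs between the KO and WT animals; it was found and tested on the same genes, without sequence to test it, and an effect of SREBP1c loss on these genes stays open as well.

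The fatty acid synthesis list was lower in replicate 2 than in replicate 1 of each group (median differences −0.313 in WT and −0.395 in KO). It was lower in KO, most in KO replicate 2. Without that library the median was −0.14, below the central 95% of 10000 random lists of matched expression (−0.06 to 0.13). The difference between the WT libraries (−0.313) lay below its random lists too (−0.10 to 0.06), so that bound alone does not mark a KO effect. WT replicate 2 lay at −0.16, and 9 of the 21 genes were lower in KO replicate 1 than in both WT libraries (33.3% by chance). KO replicate 2 alone as the source therefore cannot be told apart from a difference in both KO libraries. The comparison with WT replicate 2 was added to this test after its value was seen. Another time of day of collection may also lower these genes, although the opposite clock phases were only 0.018 apart in KO replicate 2 and −0.24 in KO replicate 1, where at least 0.5 was required. With the genes above 1 FPKM alone (Nr1d1, Nr1d2 and Tef against Arntl, Npas2 and Clock) KO replicate 2 also missed that bound (−0.20, both phases lower) and KO replicate 1 reached it (−1.08), but the gaps between single genes in KO replicate 2 ran from −1.17 to 0.38, so by a look at this spread that was added after the values were seen the explanation stays open. The loss of SREBP1c itself is the biological explanation that the design names, and these values neither exclude it nor isolate it.

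The acute phase list was high in KO replicate 2 (median 1.07) and not in KO replicate 1 (−0.27). Of its 29 genes, 7 were nevertheless higher in both KO libraries than in both WT libraries (16.7% by chance). Saa1 and Lcn2 were not among these 7. Saa1 had 65.8 and 87.3 FPKM in WT, 34.7 in KO replicate 1 and 1244 in KO replicate 2. Lcn2 had 8.99 and 15.1 in WT and 7.19 and 172 in KO, and Mt1 14.7 and 15.7 in WT and 16.1 and 292 in KO. The neutrophil genes S100a8 and S100a9 were higher in that library too, at 10.02 and 9.5 FPKM against 3.35 and 2.51 in KO replicate 1. Together they rose by 0.0829 of the rise of Lcn2, which argues against infiltrating neutrophils as its main source and not against some neutrophil RNA. The lower depth of that library is argued against by WT replicate 2, with the same implied number of fragments (21.2 M), where the list median was 0.19 above WT replicate 1, compared with 1.36 between the KO libraries. Markers of Kupffer cells and macrophages moved the same way between the KO libraries, with list medians of −0.20 in KO replicate 1 and 0.55 in KO replicate 2. An acute phase state of the animal behind KO replicate 2 may account for the acute phase values, and the design has no group with which to test it.

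Of the 3 splits of the 4 libraries into 2 and 2, 1 gave as many as 5 rows past the threshold, the real one, and the highest of the others gave 3. With 3 splits no share under 0.05 can be reached.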
